A study of Homo sapiens with 11 samples.

How the data were processed

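RNA of SH-SY5Y cells was profiled on 11 one-colour Affymetrix HG-U133 Plus 2.0 arrays. Per the labels, 2 arrays were untreated and 3 treated with nicotine at 1 mM for 1 h, and 3 were untreated and 3 treated for 24 h. The source name gives peripheral ganglion for every array, while the descriptions name SH-SY5Y. Array numbers come from the sample titles, where the title with no number is taken as array 1.

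The values were the authors' deposited intensity signals, 54675 probe sets per array, of which 62 are controls. How the authors made them is not given in the sources used here. The values are linear and never negative, and every array has the same mean of about 149.98 after 2% of the values at each end are removed, as 1 scaling factor per array would give, which was not tested. The medians still differed between arrays by up to 0.192 on the log2 scale, so the deposited intensity values were quantile normalized here and turned into log2(value + 16). Fold changes are on that scale, which understates the change of dim genes. "As deposited" means the same without quantile normalization.

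Probe sets were named from the platform's annotation: 41097 had 1 gene symbol, 1801 several and 11777 none. Of those with 1 symbol, 41043 were found by gene number in a RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols, and 54 were not. The genome build behind the probe annotation is not given in the sources used here, and no coordinates are printed. The 19775 genes were each represented by the probe set with the highest mean over all arrays. A gene was tested if it lay above an array's 40th percentile on at least 2 arrays, which left 16151 genes and removed 3624.

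Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 11 arrays, 1 mean per group, 7 residual and 3.23 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were nicotine against untreated at 1 h and at 24 h, the difference between both, and untreated cells at 24 h against 1 h. All adjusted p-values of genes come from limma, and those called adjusted over the list alone use only that list's tested genes. A set of 29 gene lists (653 entries, 586 on the array, 542 tested) covered signalling, cholinergic and catecholamine genes, stress responses, metabolism, the cell cycle, housekeeping complexes and markers of other cell types, and was tested with camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. Members of a list can move together, so counts of members in the same direction are not independent results. Errors are SE of log2 fold changes or SD of group levels, as stated.

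The groups, tests, lists and alternatives listed at the end were fixed before the data were examined, as was the rule for named genes. Genes past the threshold whose groups do not overlap and that are brighter than the median gene would be named first; where fewer than 3 pass in a direction, the 5 with the smallest p in that direction under the same conditions are named and said not to have passed. Non-overlap was not asked of the difference between both effects. Up to 4 genes of the smallest p on each list, and all tested nicotinic subunits, could be named as well.

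The alternatives were no filter and a stricter one (60th percentile), values as deposited, pseudocounts of 1 and 64, the median of all probe sets of a gene, every probe set, another variance prior, array weights, only the arrays compared, array number as a block, and leaving out each array in turn. The steps were tested on simulated data made from the measured levels, with 200 changed genes of known size: of changes of log2 2, 85% were recovered at 1 h and 88% at 24 h, each beside 10 false calls, and with no change 0 genes were called. At log2 1, 8 false calls stood beside 49 recovered genes at 1 h and 10 beside 99 at 24 h, more than the 5% aimed at. The simulated noise was drawn independently for each gene and array, without the structure that genes share on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All arrays were used, and probe sets with several or no gene symbols were left out of the gene tests.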

Results

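Gene expression was measured in SH-SY5Y cells, an established human neuroblastoma line of sympathetic lineage that is widely used as a neuronal cell model, after exposure to nicotine at 1 mM or no treatment. Nicotine activates nicotinic acetylcholine receptors, ligand-gated cation channels assembled from 5 subunits. The 11 one-colour arrays fell into 4 groups: 2 untreated and 3 nicotine-treated arrays at 1 h, and 3 untreated and 3 nicotine-treated arrays at 24 h. The study is titled as one of chronic nicotine exposure. Its design asks which transcripts differ between treated and untreated cells at each time and whether that difference depends on the time. The deposited median signal per array ran from 27.5 to 33.7. The number of arrays limits the precision of every value. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Across genes, arrays of the same group correlated at 0.961 to 0.974 over 10 pairs and arrays of different groups at 0.961 to 0.973 over 45 pairs. The ratio of 3' over 5' GAPDH signal, a sign of RNA integrity, averaged 1.31 ± 0.219 (SD, n = 2) in untreated and 1.33 ± 0.0517 (n = 3) in treated cells at 1 h, and 1.32 ± 0.103 (n = 3) and 1.28 ± 0.0425 (n = 3) at 24 h. The same ratio for ACTB averaged 2.93 ± 0.413 and 2.87 ± 0.186 at 1 h, and 3.43 ± 0.906 and 2.70 ± 0.222 at 24 h.

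The probe sets for the drug's own receptors differed widely in brightness, and several lay near the floor. CHRNA3, which encodes the alpha3 subunit of the ganglionic receptor, had a mean signal of 3274 over the 11 arrays, against 278 for CHRNA5, 141 for CHRNB2, 81.6 for CHRNB1 and 66.3 for CHRNB4. The remaining subunits with a probe set of their own, CHRNA2, CHRNG, CHRNE, CHRNA10, CHRNA6, CHRNA9, CHRNB3 and CHRND, averaged between 9.35 and 34.0. CHRNA1, the muscle alpha subunit, was too dim to be tested at 7.06. Of the 14 subunit genes with a probe set of their own 13 were tested, of which 3 were brighter than the median gene. CHRNA4 and CHRNA7 are not among the 14, and neither was tested as a gene. Signals of different probe sets are set side by side here only as brightness, since probe sets differ in how strongly they respond to their transcript.

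The first comparison asked which transcripts differed after 1 h in nicotine. No gene passed limma's moderated test at an adjusted p under 0.05 among the 16151 genes tested, where 484 had an unadjusted p under 0.05. Immediate-early genes, the transcription factors and growth regulators induced within minutes of a stimulus, were spread widely. FOS had a log2 fold change of 1.51 ± 0.95 (SE), EGR1 of 0.70 ± 0.57 and DUSP1, a phosphatase that shuts off MAP kinases, of 0.55 ± 0.36 (-0.25 with the median of its probe sets), while KLF2 lay at -0.67 ± 0.34. Of the targets of ATF4, the transcription factor of the integrated stress response, 24 of 27 were higher in treated cells, among them the alanyl-tRNA synthetase AARS1 at 0.30 ± 0.19, the cystathionine gamma-lyase CTH at 0.30 ± 0.27 (-0.05 without untreated array 2 of 1 h) and STC2 at 0.46 ± 0.43. Among hypoxia-response genes 22 of 24 were higher, with the aldolase ALDOC at 0.49 ± 0.36 and the glucose transporter SLC2A1 on the other side at -0.38 ± 0.30. Among genes of the G1/S transition and DNA replication 20 of 25 were lower, with the replicative helicase subunit MCM4 at -0.53 ± 0.19. Several of these values hung on 1 array. Without nicotine array 2 of 1 h FOS was 0.42, EGR1 0.36, DUSP1 0.14, STC2 0.24 and ALDOC 0.14. Without nicotine array 3 FOS was 2.49, EGR1 1.07, DUSP1 0.93, CTH 0.47, STC2 0.77 and SLC2A1 -0.07. Without untreated array 1 FOS was 2.45, KLF2 -0.31, CTH 0.66, ALDOC 0.77 and SLC2A1 -0.25, and without untreated array 2 FOS was 0.57, EGR1 0.46, DUSP1 0.36, KLF2 -1.04, ALDOC 0.21 and MCM4 -0.35.

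None of the 29 gene lists passed camera at 1 h with a preset correlation of 0.01, an estimated correlation or fry. The ATF4 targets came closest, with a median log2 fold change of 0.18 and an adjusted p of 0.108 (0.986 with an estimated correlation; 1.32e-06 to 0.993 over all other settings). Hypoxia genes had a median of 0.12 (adjusted p = 0.36), immediate-early genes of 0.15 and G1/S genes of -0.08 (both adjusted p = 0.476). These shifts changed with the arrays left out. Untreated array 2 and nicotine array 3 of 1 h lay together, with immediate-early mean log2 levels of 7.71 and 7.75. Untreated array 1 had 8.81, and nicotine arrays 1 and 2 had 8.75 and 8.89. In the same order, ATF4 means were 8.35 and 8.39 against 8.74, 8.87 and 8.83, and G1/S means 10.29 and 10.26 against 9.90, 9.93 and 9.83. Leaving out 1 array therefore unbalances the groups for these lists. Without untreated array 1 of 1 h, 5 lists passed, with immediate-early genes at 0.56, ATF4 targets at 0.39, G1/S genes at -0.31, histones at 0.73 and markers of substrate-adherent neuroblastoma cells at -0.39. Without nicotine array 3 of 1 h, 5 lists passed as well, with immediate-early genes at 0.32, ATF4 targets at 0.31, hypoxia genes at 0.17, G1/S genes at -0.24 and the substrate-adherent markers at -0.33. Without untreated array 2 of 1 h, the immediate-early median turned to -0.23, the ATF4 median to -0.05 and the G1/S median to 0.19. Without nicotine array 2 of 1 h the hypoxia median was 0.01, and without untreated array 1 it was 0.02. Without nicotine array 1 of 1 h the immediate-early median was -0.03, and without nicotine array 2 the G1/S median was 0.03.

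The genes picked by the naming rule at 1 h did not pass the threshold, and their adjusted p from limma ran from 0.866 to 0.999. On the higher side stood the probe set annotated to MIRLET7D, a microRNA gene, at 0.61 ± 0.20, the Golgi receptor gene GPR107 at 0.52 ± 0.19, the lysosomal enzyme gene NAGLU at 0.49 ± 0.18, NACAD at 0.55 ± 0.20 and the lipid phosphatase gene INPPL1 at 0.57 ± 0.22. On the lower side stood MT1HL1, a metallothionein pseudogene whose probes may also bind other metallothionein transcripts, at -1.04 ± 0.25, IQSEC1 at -0.60 ± 0.19, ZFPL1 at -0.51 ± 0.17, DMWD at -0.60 ± 0.19 and SMAD5, a mediator of BMP signalling, at -0.41 ± 0.13. That direction was shared by 2 of 4 probe sets of GPR107, 1 of 2 of NAGLU and IQSEC1, 1 of 3 of ZFPL1 and DMWD, and 3 of 5 of SMAD5. With the median of all probe sets of a gene, GPR107 turned to -0.22 and ZFPL1 to 0.26. Without untreated array 1 of 1 h GPR107 was 0.33 and INPPL1 0.20, and without untreated array 2 INPPL1 was 0.93, MT1HL1 -0.66 and IQSEC1 -0.38. Adjusted over the list alone, 1 gene of all lists passed: ICAM1, the intercellular adhesion molecule on the list of NF-kB and cytokine genes, at -1.37 ± 0.34 (adjusted over the list alone, adjusted p = 0.0303; over all genes 0.872). With 29 lists tried, some such calls can arise by chance. ICAM1 was dim, at a log2 level of 4.70 ± 0.29 (SD, n = 3) against 6.08 ± 0.22 (n = 2). Of its 3 probe sets 2 had that direction, and RELB on the same list lay at -0.85 ± 0.34, from -1.37 without untreated array 1 of 1 h to -0.33 without untreated array 2. The gene with the smallest adjusted p of all, EVC2, was chosen after its values were seen and was dim as well, at 0.96 ± 0.15 with an adjusted p of 0.496.

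The 1 h count of 0 can be set against the spread. Of the 484 genes at an unadjusted p under 0.05, 225 were higher and 259 lower in nicotine, where 808 are expected by chance alone. The treated and untreated arrays did not overlap in 2092 genes, or 13.0%, against 20% by chance for 3 arrays against 2. For the 8075 genes brighter than the median, the 95% interval of a log2 fold change reached 0.44 to either side (1.35-fold) in the median gene. With simulated changes of log2 1 in 200 genes, 24.5% were recovered at 1 h, beside 8 false calls, and none at log2 0.5. The simulated noise was independent between genes, unlike that of the arrays, so these rates need not hold for the real data.

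After 24 h in nicotine no receptor subunit passed over all genes. CHRNA3 had a log2 fold change of 0.11 ± 0.33 (95% interval -0.62 to 0.84), CHRNA5 of 0.00 ± 0.20 (-0.45 to 0.45), CHRNB2 of 0.47 ± 0.23 (1 of 2 probe sets in that direction) and CHRNB4 of 0.10 ± 0.25. The dim CHRNA2 lay at -0.59 (-0.31 without untreated array 2 and -0.32 without nicotine array 2 of 24 h). The 16 tested members of the list of subunits and chaperones ran from -0.89 to 0.53, with 8 higher and 8 lower. CHRNG, the gamma subunit of the fetal muscle receptor, was lower at -0.89 ± 0.16 (95% interval -1.23 to -0.54). Its log2 level was 4.81 ± 0.17 (SD, n = 3) in treated against 5.69 ± 0.14 (n = 3) in untreated cells, and all 3 treated arrays lay below all 3 untreated ones. It passed adjusted over the list alone (adjusted p = 0.00288) and not over all genes (adjusted p = 0.645). The list adjustment does not account for the 29 lists tried, over which some such calls can arise by chance. The CHRNG signal was low on every array, and the fold change moved from -1.51 with a pseudocount of 1 to -0.39 with one of 64. At 1 h CHRNG stood at -0.07 ± 0.17, and the difference between the nicotine effects of both times, -0.82 ± 0.23, did not pass (adjusted p = 1). Without nicotine array 3 of 24 h CHRNA3 turned to -0.19 and CHRNB4 to -0.08, and without untreated array 3 of 24 h CHRNA3 was 0.47. CHRNA5 ran from -0.15 without nicotine array 1 to 0.17 without nicotine array 2 of 24 h, where CHRNB4 was 0.29. At 1 h CHRNA3 lay at -0.06 ± 0.37, and at 0.00 in the values as deposited, CHRNA5 at 0.04 ± 0.22, CHRNB2 at 0.25 ± 0.26, CHRNB4 at -0.31 ± 0.28, and the dim subunits CHRNA10 and CHRNA9 at -0.63 ± 0.27 and -0.76 ± 0.34. Without untreated array 2 of 1 h CHRNB2 turned to -0.11 and CHRNA5 to -0.19, and without untreated array 1 they were 0.61 and 0.27. Without nicotine array 2 of 1 h CHRNA3 turned to 0.07, and without nicotine array 3 it was -0.17. CHRNB4 ran from -0.56 without nicotine array 1 to -0.17 without nicotine array 3, and CHRNG from -0.16 without nicotine array 3 to 0.03 without nicotine array 1.

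**Figure D1:**
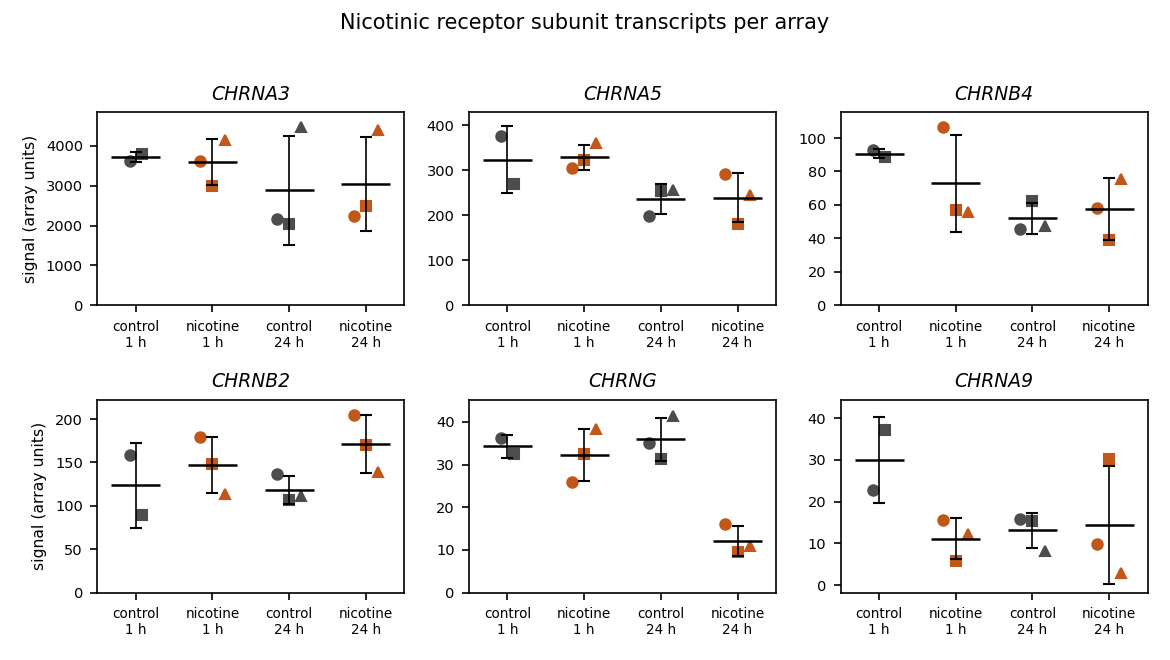
Signal per array (array units, after quantile normalization) of 6 nicotinic receptor subunit genes in the 4 groups; points are arrays (circle, square and triangle for arrays 1, 2 and 3), lines the group mean and bars the SD. At 24 h CHRNG lies lower and CHRNB2, by a narrow margin, higher on all 3 nicotine arrays than on all controls, and CHRNA3 shows the high array 3 in both 24 h groups.

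At 24 h genes of cell division stood mostly on the lower side in nicotine. Of the G1/S and DNA replication genes 23 of 25 were lower, with a median log2 fold change of -0.15, led by the replication licensing factor CDT1 at -0.62 ± 0.19, followed by the helicase subunits MCM7 at -0.27 ± 0.18 and MCM3 at -0.27 ± 0.20 and by GINS2 at -0.27 ± 0.19. Of the G2/M genes 27 of 28 were lower, with a median of -0.20, the proliferation marker MKI67 at -0.34 ± 0.36 (-0.07 without untreated array 1 or nicotine array 3 of 24 h, -0.71 without untreated array 3) and the mitotic kinase PLK1 at -0.32 ± 0.41 (0.08 without nicotine array 3 of 24 h, -0.04 without untreated array 1, -0.60 without untreated array 3 and -0.63 without nicotine array 1). Neither list passed camera (adjusted p = 0.0725 for G1/S and 0.532 for G2/M, and 0.974 for each with an estimated correlation). The estimated correlation between members was 0.394 for G1/S and 0.847 for G2/M. Their members move together, so the counts of lower members are not independent results. The G1/S list passed in 8 of 18 other settings, among them each of those without untreated array 1 or 2 of 1 h, nicotine array 3 of 1 h, or nicotine array 1 or 2 of 24 h. Leaving out a 1 h array does not change the 24 h fold changes, only the error estimate, so those passes do not repeat the shift. Over all settings the G1/S median stayed between -0.16 and -0.07 and its adjusted p between 0.0164 and 0.994. The G2/M median hung on the arrays numbered 3: it passed at -0.50 without untreated array 3 of 24 h, and at 0.20, in the other direction, without nicotine array 3 of 24 h. It lay at 0.02 without untreated array 1 of 24 h. It also passed at -0.43 without nicotine array 1 and at -0.34 without nicotine array 2 of 24 h. Both arrays numbered 3 were low, so leaving out 1 of them unbalances the groups. The G2/M means were 10.58, 10.37 and 9.47 on untreated arrays 1 to 3 and 10.48, 10.26 and 9.14 on nicotine arrays 1 to 3. In both lists each nicotine array lay below the untreated array of its number. With array number as a block within each time point both lists passed, though the labels do not give pairs.

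The other lists at 24 h did not pass either. Cholesterol synthesis genes had a median of 0.07 with 16 of 19 higher (adjusted p = 0.532), and passed at 0.16 without nicotine array 2 of 24 h. Markers of blood and endothelial cells lay at -0.29 (adjusted p = 0.607), those of Schwann cells and glia at -0.10 and those of substrate-adherent neuroblastoma cells and fibroblasts at 0.01. Among stress lists the medians were -0.04 for ATF4 targets (0.03 without untreated array 3 and 0.04 without nicotine array 1 of 24 h), 0.00 for the unfolded protein response (0.12, and past the test, without untreated array 3 of 24 h), -0.01 for NRF2 targets (0.00 as deposited), -0.04 for heat shock proteins, 0.07 for metallothioneins, -0.02 for hypoxia genes and 0.06 for p53 targets. Signalling lists gave 0.00 for immediate-early genes (0.02 in the values as deposited), -0.01 for MAP kinase feedback genes, -0.02 for NF-kB genes and 0.06 for interferon genes. Neuronal lists gave -0.01 for receptor subunits and chaperones (0.01 as deposited), 0.04 for cholinergic, 0.02 for catecholamine and -0.05 for neuropeptide genes, and -0.03 for the neuronal cytoskeleton, whose test pointed up. Housekeeping lists gave 0.01 for the proteasome, -0.01 for lysosomes, 0.00 for fatty acid synthesis, 0.11 for histones, -0.03 for splicing factors and 0.00 for oxidative phosphorylation, whose test pointed up. Ribosomal protein genes had a median of 0.00 at 24 h and 0.01 at 1 h, but of 0.16 and 0.25 in the values as deposited, where they passed the test. Several medians at 24 h changed sign over the other settings without passing in any. They ran from -0.09 to 0.29 for cholinergic genes, -0.07 to 0.14 for catecholamine genes and -0.24 to 0.19 for substrate-adherent markers. Immediate-early genes ran from -0.11 to 0.12 and histones from -0.05 to 0.22.

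No gene passed limma at 24 h (0 of 16151), and the counts gave 586 genes at an unadjusted p under 0.05 (253 higher, 333 lower), or 3.63%. Treated and untreated arrays did not overlap in 1395 genes, or 8.64%, against 10% by chance. The naming rule picked the oxysterol-binding gene OSBPL7 at 0.47 ± 0.15, the hedgehog acyltransferase HHAT at 0.48 ± 0.15, COMMD8 at 0.55 ± 0.19, METTL8 at 0.38 ± 0.13 and UBE2NL at 0.50 ± 0.18 on the higher side. On the lower side it picked the lysophospholipid acyltransferase LPCAT3 at -0.81 ± 0.24, INAFM2 at -0.46 ± 0.14, the phosphatase CTDNEP1 at -0.47 ± 0.15, CDT1, and MPP2 at -0.46 ± 0.15. All of them had an adjusted p of 1, and 1 of the 3 OSBPL7 probe sets and 1 of the 2 LPCAT3 probe sets had the direction given. With the median of all probe sets OSBPL7 turned to -0.15 and LPCAT3 moved to -0.11. The smallest adjusted p, 0.341, was that of ADAMTS9-AS1, a dim antisense transcript chosen after its values were seen, at -1.21 ± 0.16. Leaving out untreated array 1 of 24 h gave 1 gene, EVPL, which was lower. For genes brighter than the median the 95% interval reached 0.39 to either side (1.31-fold), and none of them differed by more than log2 1. At 24 h 49.5% of simulated changes of log2 1 were recovered beside 10 false calls, again with noise independent between genes.

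Whether nicotine acted differently at 24 h and 1 h was tested as the difference of the 2 effects. No gene passed limma, with 531 genes (3.29%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.61. No list passed camera, with ATF4 targets closest at a median of -0.20 (adjusted p = 0.284). The rule named OSBPL7 at 0.71 ± 0.22, the actin pseudogene ACTBP9 at 1.04 ± 0.32, the ubiquitin ligase TRIM32 at 0.68 ± 0.21, the choline kinase CHKA at 0.80 ± 0.25 and FEM1C at 0.76 ± 0.24, which had the more positive nicotine effect at 24 h. It named GPR107 at -0.90 ± 0.25, FKBPL at -1.16 ± 0.34, TSPAN31 at -0.99 ± 0.31, STON2 at -0.98 ± 0.30 and the JNK scaffold gene MAPK8IP2 at -0.67 ± 0.21 on the other side, all with an adjusted p of 1. Only 1 of 2 probe sets of TRIM32 and TSPAN31 had that direction. With the median of all probe sets OSBPL7 turned to -0.26 and GPR107 to 0.20, and without untreated array 1 of 1 h FEM1C was 0.50. Across all tested genes, which are not independent replicates, the nicotine effects at 1 h and 24 h correlated at a Pearson r of 0.0155 (Spearman rho 0.0372), and 52.4% of genes had the same sign. Among genes brighter than the median r was 0.103 and 54.1% had the same sign. The effects at both times share no array.

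Between untreated cells at 24 h and 1 h, 3 gene lists passed camera with the preset correlation, and none with an estimated correlation or with fry. Of the immediate-early genes 31 of 32 were lower at 24 h, with a median log2 difference of -0.85 (adjusted p = 5.13e-19, and adjusted p = 0.48 with an estimated correlation). EGR1, a zinc-finger factor induced by growth factors and depolarization, went from a log2 level of 12.19 ± 0.35 (SD, n = 2) to 8.74 ± 0.95 (n = 3), a difference of -3.45 ± 0.57. ID1, a BMP target that blocks differentiation factors, differed by -2.52 ± 0.45, the matricellular gene CCN1 by -2.04 ± 0.40 and the Notch target HES1 by -1.44 ± 0.36. Of the genes of the unfolded protein response 19 of 22 were lower, with a median of -0.33 (adjusted p = 2.85e-06, and adjusted p = 0.752 with an estimated correlation), among them the endoplasmic reticulum chaperones HSPA5 at -0.61 ± 0.27 and HSP90B1 at -0.77 ± 0.26, HERPUD1 at -0.57 ± 0.25 and XBP1 at -0.57 ± 0.26. Untreated array 3 of 24 h stood apart: its mean log2 level of this list was 9.63, against 9.63 and 9.72 at 1 h and 9.17 and 9.27 on the other untreated arrays of 24 h. Of the G2/M genes 28 of 28 were higher, with a median of 0.51 (adjusted p = 1.67e-06, and adjusted p = 0.752 with an estimated correlation), among them CDC20 at 0.98 ± 0.42, PLK1 at 1.02 ± 0.46, UBE2C at 0.67 ± 0.34 and CCNB2 at 0.61 ± 0.32. Here too untreated array 3 stayed at the 1 h level, with a list mean of 9.47 against 9.43 and 9.77 at 1 h and 10.58 and 10.37 on the other 2 arrays, so the higher level rests on 2 of 3 arrays. Without untreated array 1 of 1 h HSP90B1 was -0.31, HERPUD1 -0.32, CDC20 0.39, PLK1 0.52 and UBE2C 0.31. Without untreated array 2 of 1 h HSP90B1 was -1.23, CDC20 1.57 and UBE2C 1.02, and without untreated array 1 of 24 h XBP1 was -0.37.

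Over all other settings the adjusted p ran from 2.11e-26 to 0.48 for immediate-early genes, from 1.06e-10 to 0.752 for the unfolded protein response and from 5.22e-27 to 0.771 for G2/M. Fry, which does not compare a list with other genes, gave adjusted p of 0.41, 0.536 and 0.771 for these lists. Adjusted over the list alone, 13 of the 32 immediate-early genes passed, 1 of them higher, with EGR1 and ID1 at adjusted p = 0.00321, against 0 of the 22 unfolded protein response and 0 of the 28 G2/M genes, and none passed over all 16151 genes. These 3 lists stayed past the test without any single array. The number that passed went from 3 to 6 without untreated array 1 of 1 h, and to 5 without untreated array 2 of 1 h, untreated array 1 or untreated array 3 of 24 h. Without untreated array 1 of 1 h the immediate-early median was -0.48. Over all other settings the medians ran from -1.32 to -0.48 for immediate-early genes, from -0.46 to -0.19 for the unfolded protein response and from 0.28 to 0.84 for G2/M.

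**Figure D2:**
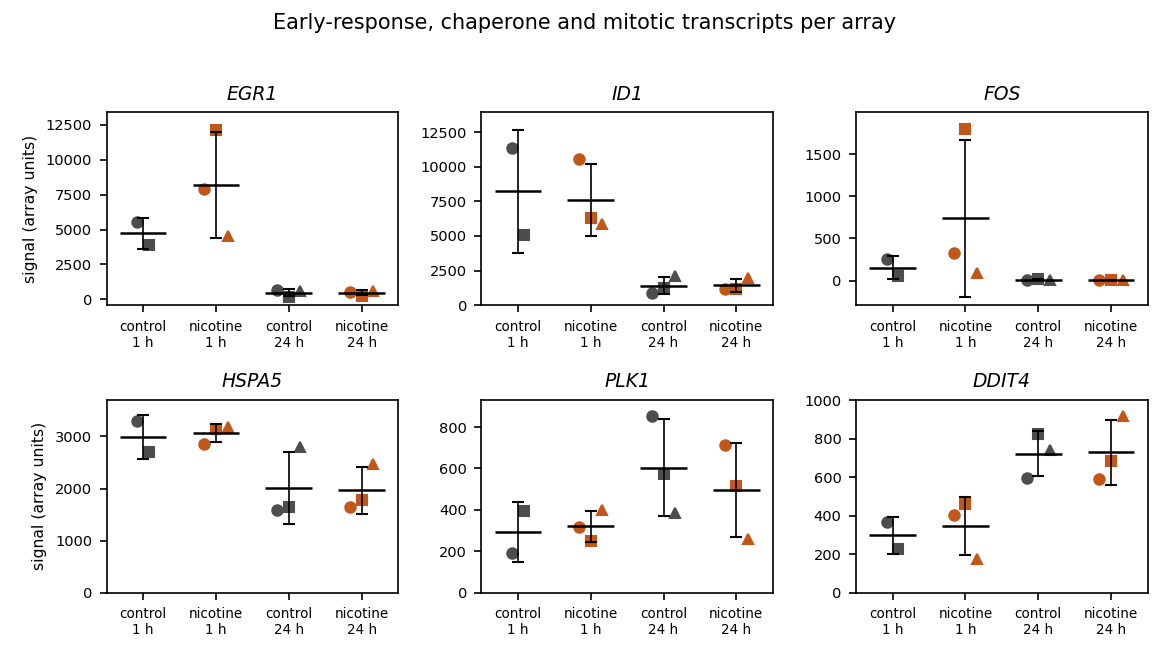
Signal per array (array units, after quantile normalization) of 6 transcripts in the 4 groups, with arrays as points (circle, square and triangle for arrays 1, 2 and 3), the mean as a line and the SD as a bar. EGR1 and ID1 sit lower and DDIT4 higher on all 24 h arrays, HSPA5 stays near its 1 h level on both 24 h arrays numbered 3, and FOS has 1 nicotine array of 1 h far above all others.

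The other lists in the untreated cells did not pass. Hypoxia genes had a median of 0.21 and proteasome subunits of -0.07 (both adjusted p = 0.0802), cholesterol genes of -0.13 and G1/S genes of -0.06 (both 0.127), neuropeptide genes of -0.27 (0.151) and ATF4 targets of -0.15 (0.212), with DDIT4, an inhibitor of mTORC1, at 1.25 ± 0.38 and the amino acid transporter chain SLC3A2 at -0.67 ± 0.21. Without untreated array 1 of 1 h the ATF4 median was 0.18, and without untreated array 2 the G1/S median was 0.17. Without untreated array 2 of 1 h the ATF4 targets passed at -0.41 and cholesterol genes at -0.20. Of the cell-type markers, those of substrate-adherent neuroblastoma cells and fibroblasts lay at -0.21 (0.127), with lumican, LUM, at -1.01 ± 0.24 (adjusted over the list alone, adjusted p = 0.0306), and those of Schwann cells and glia at 0.37 (0.258). The substrate-adherent median hung on the untreated arrays of 1 h: without array 1 it passed at -0.43, and without array 2 it turned to 0.11. Without untreated array 3 of 24 h it passed at -0.43, and without untreated array 1 of 24 h it was -0.01. Hypoxia genes passed in 5 of 18 other settings, at 0.28 without untreated array 3, 0.24 without untreated array 1 of 24 h and 0.21 without nicotine array 2 of 1 h, and lay at 0.09 without untreated array 2 of 24 h and at 0.12 without untreated array 1 of 1 h. Leaving out a nicotine array does not change the fold changes of untreated cells, only the error estimate. Every further list had an adjusted p of 0.258 or more. For catecholamine genes (median -0.06, test up) and lysosome genes (0.04, test down) the median and the test differed in sign, as they did at 1 h in nicotine for lysosome, heat shock and cholinergic genes.

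No single gene passed limma between 24 h and 1 h in untreated cells, where 789 genes (4.89%; 404 higher, 385 lower) had an unadjusted p under 0.05 and 3203 genes (19.8%) did not overlap, against 20% by chance. Beside EGR1 and ID1, the rule named ID2 at -1.41 ± 0.25, the homeobox gene MSX2 at -1.84 ± 0.36 and ACTBP9 at -1.23 ± 0.24 on the lower side, and LRRC37A2 at 0.74 ± 0.14, ZC3H6 at 0.97 ± 0.20, NOTCH2NLA at 0.75 ± 0.16, the ubiquitin ligase RNF145 at 0.93 ± 0.22 and the pseudogene HERC2P7 at 0.70 ± 0.17 on the higher side. Their adjusted p from limma ran from 0.583 to 0.765, and without untreated array 1 of 1 h RNF145 was 0.59. ACTBP9, LRRC37A2, NOTCH2NLA and HERC2P7 have near-identical copies elsewhere in the genome that their probes may also detect. Time point and any batch of culture or hybridization cannot be told apart here, since the labels used give no batch or date.

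**Figure D3:**
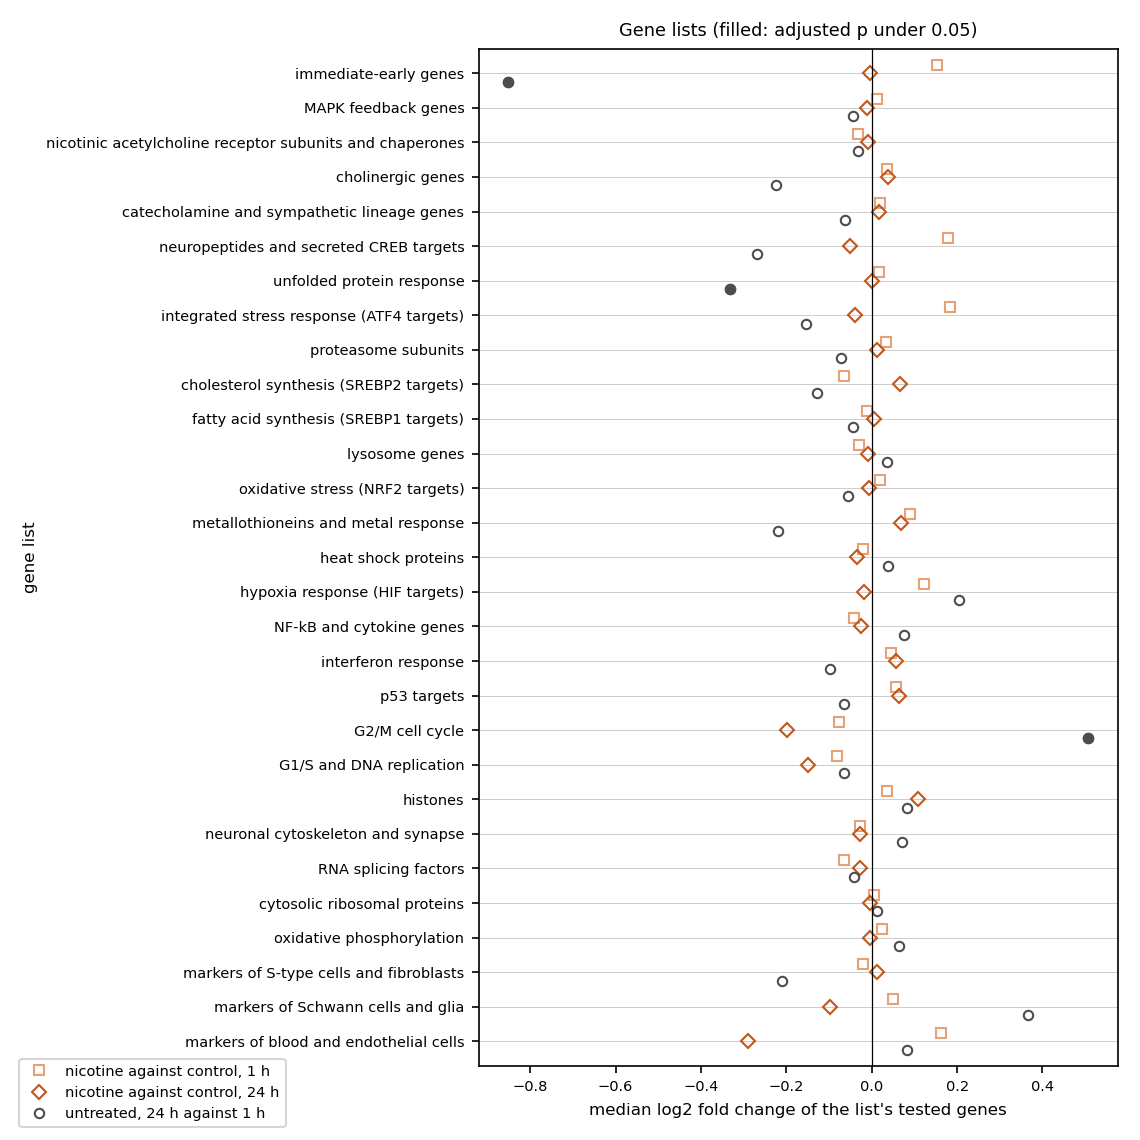
Median log2 fold change (x axis) of the tested genes of each of the 29 lists (y axis) for nicotine against control at 1 h and 24 h and for untreated cells at 24 h against 1 h; filled symbols passed camera with a preset correlation. Only immediate-early, unfolded protein response and G2/M genes of the untreated comparison are filled, at -0.85, -0.33 and 0.51.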

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

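The tests of the patterns weighed here were chosen only after the results were seen, except the counts over other splits of the arrays.

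On nicotine array 2 of 1 h, the control probe set for the 5' part of 18S ribosomal RNA, which enters no comparison, had a signal of 3827. It stood out because the untreated arrays of 1 h had 396 and 1057, and the other nicotine arrays of 1 h 1509 and 384. The probe sets for the middle and 3' part of 18S reached 695 and 480 on the same array, against at most 503 and 275 in the untreated arrays of 1 h.

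A first pattern is that the 1 h arrays part across the treatment: setting untreated array 2 and nicotine array 3 against the other 3 gave 201 genes past limma's threshold and 2888 at an unadjusted p under 0.05, against 0 and 484 for the real split. That points to a structure of the samples, and all 10 splits of these arrays gave at least 484, though with 10 splits the share cannot go under 0.1. On genes lower at 24 h, untreated array 2 and nicotine array 3 lay 0.478 and 0.417 of the way from the other 1 h arrays to 24 h arrays 1 and 2. On genes higher at 24 h they lay at 0.407 and 0.416. The other 1 h arrays lay from -0.258 to 0.0736 and from -0.138 to 0.176. The cause of these positions was not tested. Over all 11 arrays, the first component of the values centred by group (25.7% of the variance) went with the log2 18S signal at a Pearson r of 0.861 (exact within-group permutation p = 0.00463, adjusted 0.0123 over 8 relations; Spearman rho 0.8, permutation p = 0.0231), at 0.776 without the 2 arrays farthest in 18S, but at 0.41 within the 7 arrays on its positive side, so it rests partly on the 4 others, which all had 18S below their group mean. RNA degradation was not excluded: r with the 3' over 5' ratio was -0.0811 (exact permutation p = 0.859) and -0.506 without the 2 farthest arrays. Ribosomal RNA in the labelled material is consistent with the pattern, a poly(A) spike control went with the component as well (r = -0.791, adjusted p = 0.0123), and no biological explanation was tested.

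A second pattern is that both 24 h arrays numbered 3, untreated and nicotine, deviate from their groups together (correlation across genes 0.297). Against the other 24 h arrays 0 genes passed limma (2363 at an unadjusted p under 0.05) and 5 lists passed camera: G2/M genes at -1.07 (adjusted p = 5.35e-32), the unfolded protein response at 0.38 (2.41e-07), substrate-adherent markers at 0.53 (9.32e-06), ATF4 targets at 0.22 (0.00409) and immediate-early genes at 0.21 (0.0192), all lost with an estimated correlation (adjusted p = 0.422 for G2/M, unfolded protein response and immediate-early genes, 0.474 and 0.805 for the others). Ribosomal RNA may account for part of it, but is not singled out. With 18S as a covariate the correlation was 0.0992 (exact within-group permutation p = 0.0162, counted on the low side only). It was 0.227 with the 3' over 5' ratio and 0.237 with the hybridization control. With the poly(A) spike signal it was reversed, at -0.237. Only 18S was permuted. Both arrays lie farther out on component 2 (18.8 and 29.0) than on component 1 (-14.4 and -16.9). Component 2 goes with the hybridization control (r = -0.779, permutation adjusted p = 0.0123) and not with 18S (r = -0.0884). That they are 1 h arrays under 24 h labels is argued against: 9 and 11 of 32 immediate-early members lay below every 1 h array by more than the member's SD over the 1 h arrays, against at most 3 for a 1 h array set against the other 1 h arrays, and EGR1 was 562 and 628 against at least 3920 at 1 h. That count was chosen after a weaker test, in which the list's mean lay below the lowest 1 h array by 0.403, less than the SD of the 1 h arrays (0.597), and genes higher on the other 24 h arrays put both near 1 h, at 0.146 and -0.222 of the way from 1 h to 24 h, against 0.749 and 0.736 for genes lower there; the higher immediate-early list goes that way too, and a shared day of culture stays open, untested.

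For the nicotine comparison at 24 h, all 10 splits of the 6 arrays gave 0 genes past the threshold like the real one (highest other 0), 5 of 10 gave at least its 586 genes at an unadjusted p under 0.05 (highest other 1228), and all 10 gave at least its 0 lists (highest other 4). Any split meets a count of at least 0, so the comparisons of called genes and of lists could not come out otherwise and decide nothing. For the unadjusted count, with 10 splits the share cannot go under 0.1.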

How the results depend on the processing

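Chosen only after the results were seen were the 18S covariate, leaving out both 24 h arrays numbered 3, and leaving out untreated array 2 and nicotine array 3 of 1 h together; all other settings, 28 in total with these, were planned. Limma's gene counts were 0 in every comparison and setting, except that a pseudocount of 1 gave 1 gene in each of nicotine at 1 h (EVC2), nicotine at 24 h (ADAMTS9-AS1) and untreated time (EVC2), nicotine at 24 h ranged from 0 to 1 over the arrays left out, and untreated time gave 6 without the 1 h pair. The cause was not tested. The correlation of both nicotine effects ran from -0.0143 to 0.0347 without single arrays, which gives a jackknife SE of 0.0432. That SE is made from these same values, so that they lie within it is no test of them. Signal over background limits the dim genes: most subunits lie near the pseudocount.

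Gene lists past camera at 1 h in nicotine numbered 0 as reported, 1 as deposited and 0 to 5 without single arrays. At 24 h they numbered 0 as reported, 2 as deposited, 1 with the 18S covariate and 0 to 3 without single arrays. In untreated time they numbered 3 as reported, 5 without both 24 h arrays numbered 3, 5 without the 1 h pair, 7 with the 18S covariate, 0 with an estimated correlation, 0 with fry and 3 to 6 without single arrays. The cause was not tested.

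Array numbers were not taken as pairs: same-numbered arrays deviated together at 24 h (correlations 0.16, 0.0907 and 0.297) but not in both pairs at 1 h (0.218 and -0.169), though every 24 h array correlated best with its own number among those of its time, a hint from the data and not the design. With the number as a replicate block within each time point, gene counts stayed 0, and 6 lists passed for nicotine at 1 h and 2 at 24 h. Untreated cells of 1 h have no array 3, so this block takes up nicotine array 3 of 1 h. What is left at 1 h is 2 arrays against 2, with the fold changes found without that array and another error estimate. CHRNA5 at 1 h was -0.0232 in both settings, and -0.0110 with a block across both times.

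Of the values of the 36 genes followed at 1 h, 793 of 813 kept their direction and side of the threshold, as did 628 of 658 of 29 genes at 24 h, 239 of 241 of 11 genes for the difference and 528 of 529 of 23 genes in untreated time. With a pseudocount of 1, EVC2 at 1 h and ADAMTS9-AS1 at 24 h were called, and the others turned direction without being called. Part of these counts was fixed in advance. Leaving out arrays that a comparison does not use cannot change its fold changes, nor can another variance prior or only the arrays compared. As no gene passed as reported, a change of side could only be a new call. With the median of all probe sets, GPR107 at 1 h was -0.22, ZFPL1 0.26, DUSP1 -0.25, OSBPL7 at 24 h -0.15, CHRNA10 0.0856 and CHRNA3 -0.0671, OSBPL7 in the difference -0.26 and GPR107 0.20, and CCNB2 in untreated time -0.0685. As deposited, CHRNA3 at 1 h was 0.00284 and CHRNA9 at 24 h 0.0227. With a pseudocount of 64, CHRNA6 at 1 h was 0.00418 and CHRNA9 at 24 h 0.00914, and with one of 1 CHRNA5 at 24 h was -0.000731. With array weights, CHRNA5 at 24 h was -0.0605, CHRNA9 0.11 and CHRNB4 -0.0138. Without both 24 h arrays numbered 3, CHRNA9 was 0.13, CHRNB1 0.0764 and CHRNB4 -0.12, and without the 1 h pair CHRNA5 at 1 h was -0.25. Without single arrays at 1 h, CHRNA2 ran from -0.0607 to 0.46, CHRNA3 from -0.17 to 0.0672, CHRNA5 from -0.19 to 0.27, CHRNA6 from -0.21 to 0.16, CHRNB2 from -0.11 to 0.61, CHRND from -0.10 to 0.45, CHRNG from -0.16 to 0.0290 and CTH from -0.0497 to 0.66. At 24 h, CHRNA3 ran from -0.19 to 0.47, CHRNA5 from -0.15 to 0.17, CHRNA9 from -0.38 to 0.26, CHRNB1 from -0.19 to 0.13, CHRNB3 from -0.0846 to 0.39, CHRNB4 from -0.0792 to 0.29 and PLK1 from -0.63 to 0.0754. The cause was not tested.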

Other observations

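All tests of this part were chosen only after the results were seen. Averaged over treated and untreated cells, 24 h against 1 h gave 7 genes past limma's threshold, all lower at 24 h. EGR1 was 13.4-fold lower (log2 difference -3.75 ± 0.38 SE, adjusted p = 0.0262), and lower too were ID1 at -2.45 ± 0.30, ID2 at -1.36 ± 0.17, CCN1 at -2.08 ± 0.27 and DUSP10, a phosphatase of stress-activated kinases, at -1.10 ± 0.14, with ADAMTS9-AS1 at -0.96 ± 0.12 and CRISPLD1 at -0.73 ± 0.09 (adjusted p = 0.0341 for these 6). The ADAMTS9-AS1 average rests more on the nicotine-treated cells, where the difference was -1.60 ± 0.16, than on the untreated ones. The count was 0 without untreated array 1 of 1 h, nicotine array 1 of 1 h, or nicotine array 1 or 2 of 24 h, 1 without nicotine array 3 of 1 h or untreated array 1 or 2 of 24 h, 2 without nicotine array 2 of 1 h or nicotine array 3 of 24 h, 3 without untreated array 3 of 24 h, and 15 without untreated array 2 of 1 h, which kept 5 of the 7 and in which 9 of the 15 were lower and the rest higher. With the 18S signal as a covariate it was 0, with 1961 genes at an unadjusted p under 0.05 against 1536 without.

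The same average gave 7 lists past camera. Immediate-early genes (30 of 32 lower, adjusted p = 1.75e-25, 0.243 with an estimated correlation), the unfolded protein response (-0.34, 3.87e-08), ATF4 targets (-0.28, 6.64e-04), proteasome subunits (-0.10, 0.00948), G1/S genes (-0.10, 0.012) and neuropeptide genes (-0.26, 0.0247) were lower, and G2/M genes higher (0.48, 2.34e-08). With an estimated correlation none passed, the smallest adjusted p being 0.243. With the 18S signal as a covariate the ATF4 targets no longer passed (-0.17, adjusted p = 0.165), as the median came nearer to 0, while proteasome subunits (-0.17) and G1/S genes (-0.27) moved away from it. Added were substrate-adherent and fibroblast markers (-0.36, 18 of 19 lower, adjusted p = 3.63e-04), hypoxia genes (0.22, 0.0122), the neuronal cytoskeleton (0.16, 0.0259) and lysosome genes (-0.14, 0.0455), so that 10 lists passed, and none with an estimated correlation (smallest adjusted p = 0.151). In the nicotine-treated cells alone 1 gene passed, ADAMTS9-AS1 at -1.60 ± 0.16 (adjusted p = 0.0279). Nicotine averaged over both times gave 0 genes by limma, with 530 at an unadjusted p under 0.05, and 1 list, G1/S genes, at -0.09 with 23 of 25 lower (adjusted p = 0.0212, 0.958 with an estimated correlation). The covariate ended that call, at a median of -0.05 with 19 of 25 lower (adjusted p = 0.668).

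Another pattern is the lower level of immediate-early genes at 24 h in untreated cells. An accident of the 2 untreated 1 h arrays is argued against by the nicotine-treated cells, which share no array with them: there the list's median was -1.14 (adjusted p = 1.79e-20, 0.314 with an estimated correlation) and 19 of 32 members passed adjusted over the list alone. With the 5' 18S signal as a covariate the median in untreated cells was -0.72 (camera adjusted p = 1.69e-11, 0.406 with an estimated correlation). Then 4 of 32 members passed adjusted over the list alone, against 13 without it. The shift was thus not removed by this signal. That does not decide whether ribosomal RNA was the whole cause, since the signal comes from 1 probe set and an imprecise covariate adjusts too little. Time itself against handling stays open as well. The labels used give no day of collection or hybridization, so an effect of another day cannot be told apart from time.

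FOS varied widely within a group, with signals of 324, 1801 and 86.1 on the nicotine arrays of 1 h, against 251 and 56.8 on the untreated arrays of 1 h and at most 12.8 at 24 h.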
